A study of Mus musculus with 14 samples.

How the data were processed

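RNA was sequenced from cultured proliferating keratinocytes and from epidermis of newborn mice, in each case from the control genotype, in which Trp63 keeps exon 13 (p63alpha), and from mice in which a KRT14-driven Cre recombinase removes that exon (p63beta). There were 3 libraries per genotype from keratinocytes and 4 per genotype from epidermis. Per the labels, the material was newborn, but they do not say whether each library came from a separate animal, so p-values measure the spread between these libraries.

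For keratinocytes, the authors deposited counts of read pairs per RefSeq gene, which per the file headers came from featureCounts 1.5.2 with strand setting 2, a minimum overlap of 25 bases and both ends mapped. The authors also deposited FPKM values for keratinocytes, and recomputing them from the counts, gene lengths and library totals gave the deposited values. For epidermis, the authors deposited expected counts estimated by salmon per gene and per transcript. The deposited TPM of the same libraries summed to the same total in each column. The authors deposited a result table of DESeq2 for each kind of sample, with a log2 fold change and an adjusted p-value per gene. The version of salmon and of DESeq2 used by the authors is not given in the sources used here. The 14 per-library columns of normalised values in those result tables were not used. The genome build was mm10 in both cases.

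The keratinocyte table held 27179 genes. For epidermis there were 24411 genes and 35034 transcripts. Genes of both tables were joined by Entrez ID through RefSeq accessions, which gave 23395 genes in both. Among the keratinocyte results, 27 gene symbols had been turned into dates, so identifiers were used instead. Mitochondrially encoded genes were in neither count table, so their share was not analysed here. Raw reads were not used here.

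Each kind of sample was fitted alone with edgeR 4.0.16 in R 4.3.3. The fit used TMM normalisation, the filterByExpr filter by group, robust quasi-likelihood dispersion and the quasi-likelihood F test. P-values were adjusted by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Log2 fold changes are p63beta over p63alpha, with a standard error (SE) from the fit. Levels are given in CPM, as mean and standard deviation (SD) over the libraries of a group. Library totals were 20688027 to 30066041 counted read pairs in keratinocytes and 21290068 to 44909629 estimated counts in epidermis. The difference between the effects in epidermis and in keratinocytes was tested with an interaction term in a joint edgeR fit of all 14 libraries over the genes of both tables.

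Before the data were examined, 38 gene lists with 755 genes were written from general knowledge of skin, matrix and other cell types, and 745 of these genes were in a table. A list with at least 5 tested genes was tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with adjustment over the lists of that comparison. Camera compares the genes of a list with all other genes tested. Each list was also tested with camera at an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance. The series title names matrix genes in keratinocytes, so the matrix lists are not independent evidence of direction in these libraries.

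The Trp63 transcripts of the epidermis transcript table were assigned to the alpha, beta or gamma ending from the annotated exons and, for transcripts with the same annotated match, from the difference in effective length between transcripts. Effective lengths were recovered from transcript counts and TPM. Shares of the Trp63 TPM were compared by a two-sided exact permutation test over the 70 splits of 8 libraries, whose smallest possible p is 0.0286, with adjustment over the 3 endings.

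The rule for naming genes was also written before the data were examined. It takes Trp63, the 10 largest rises and falls among called genes without overlap between groups and with a mean of at least 5 CPM, up to 5 genes per called list and 2 per list without a called gene. It also takes the genes called in both kinds of sample, and the 5 genes in each direction with the lowest p for the interaction. Unnamed gene models and pseudogenes were left out. The text names only part of what that rule gives, because the lists alone give far more genes than can be described. That part was picked after values were seen, so the named list members are examples rather than a complete account. D630023F18Rik, Antxr1 and Pmel in keratinocytes lie outside the rule and were chosen after their values were seen.

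Alternatives set before the data were examined were RLE size factors, no filter on low counts, leaving out each library, DESeq2 1.42.0, no robust estimation and limma on log2 FPKM or TPM with a pseudocount of 1 or 0.1. Others set then were a 2-fold minimum change, an estimated correlation, fry, the matrix list without fibroblast genes, and a block for the replicate number in keratinocytes. For the interaction, limma voom with quality weights was also set then. Alternatives added after the data were seen were a term for library batch, the first batch alone, leaving out libraries WT3 and EP12 together, the block without each replicate pair, the block with an estimated correlation, and lists without their called genes. Batch was read from the column names of the epidermis tables, where 3 libraries per genotype share one prefix (first batch) and 1 per genotype another (WT3 and KO2).

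The scripts were tested on simulated data with the dispersion of these libraries. In keratinocytes, edgeR recovered 47.8% of genes changed by a log2 fold of 1 and 90.9% of those changed by 3, with 9 unchanged genes called. In epidermis, edgeR recovered 32.8% and 95.5%, with 6 unchanged genes called, and the interaction test 10.4% and 71.2%, with 4. DESeq2 recovered 58.2% and 95.5% in keratinocytes but called 59 unchanged genes, and in epidermis it recovered 40.3% and 100% and called 34. The tests were first written to stop if any tool exceeded a bound on such calls. DESeq2 exceeded it, after which the bound was applied to edgeR alone. A shift of 0.5 on the log2 scale in the matrix core list was called with an estimated correlation in simulated keratinocytes (adjusted p 0.00546) and epidermis (3.59e-04). Simulated libraries have independent genes, unlike real ones. The changed genes, 67, 67 and 66 for log2 folds of 1, 2 and 3, left out genes of the lowest levels. No pairs or batches were simulated, so recovery in the real libraries may be lower. The floor of a gene without counts is 3 counts per library and covers counting error only. The SD and SE values include the spread between libraries.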

Results

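The transcription factor p63 has alternative C-termini, and exon 13 of Trp63 encodes part of the alpha ending. The series compares RNA from newborn mice whose Trp63 keeps exon 13 (p63alpha, the floxed control) with RNA from mice that also carry KRT14-Cre and so lose it in KRT14-expressing cells (p63beta). Cultured proliferating keratinocytes gave 3 p63alpha and 3 p63beta libraries, and epidermis gave 4 and 4. Keratinocyte p63alpha libraries 1, 2 and 3 held 24429875, 30066041 and 20688027 counted read pairs, and p63beta libraries 1, 2 and 3 held 27597913, 25455374 and 29229809. The epidermis columns are named WT or KO, which were read as p63alpha and p63beta because the header of the keratinocyte count file ties those words to these genotypes. In epidermis, the p63alpha libraries EP07, EP08, WT3 and EP09 held 34144606, 29550626, 32298763 and 21290068 estimated counts. The p63beta libraries KO2, EP10, EP11 and EP12 held 44909629, 23877821, 31128948 and 23280242.

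The first question was whether the transcripts show the intended change in Trp63 (Entrez 22061). Exon 13 spans 94 bases on chromosome 16, from 25886206 to 25886299 in mm10, in an annotated transcript with 14 exons. In epidermis, transcripts with the alpha ending carried 82.7% ± 2.20 (SD, n = 4) of the Trp63 TPM in p63alpha and 4.81% ± 4.58 (SD, n = 4) in p63beta (exact permutation p 0.0286, adjusted 0.0429). Transcripts with the beta ending carried 10.2% ± 1.88 in p63alpha and 85.1% ± 5.03 in p63beta (SD, n = 4 each, exact permutation p 0.0286, adjusted 0.0429). The gamma ending carried 7.05% ± 1.95 and 10.1% ± 3.89 (SD, n = 4 each, exact permutation p 0.2, adjusted 0.2), a difference within the spread of the libraries. That sum hides a change between gamma transcripts with the same annotated match. A first stood at 8.19 to 14.1 TPM in p63alpha libraries and at 0 in every p63beta library. Another stood at 0 to 1.49 TPM in p63alpha and at 14.4 to 48.1 TPM in p63beta. Whether the estimates of these transcripts can be told apart was not tested. In the first batch alone, with 3 libraries per genotype, the alpha ending carried 83.4% and 2.52%, and in the other batch, with 1 per genotype, 80.8% and 11.7%. The keratinocyte table has no transcript values, so the loss of exon 13 was not analysed there.

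**Figure D1:**
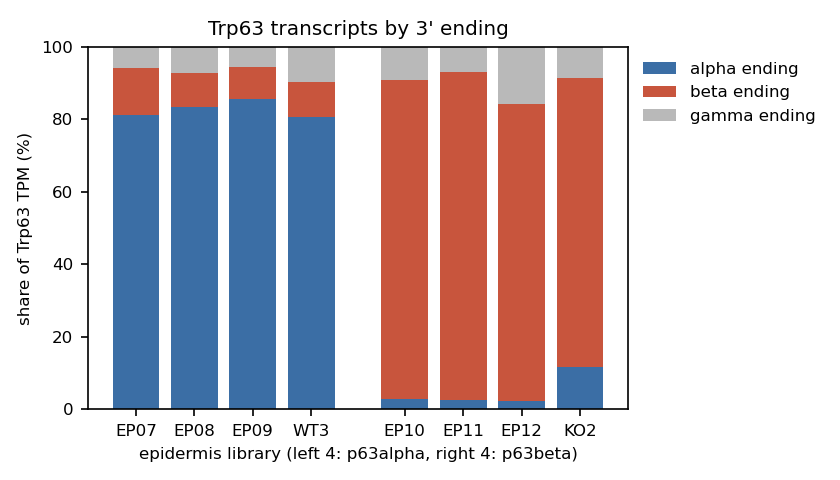
Share of the Trp63 TPM (percent) carried by transcripts with the alpha, beta or gamma ending in epidermis, by genotype. Each stacked bar is a single library, with p63alpha on the left and p63beta on the right (n = 4 each). The alpha ending averaged 82.7% in p63alpha and 4.81% in p63beta libraries.

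The total level of Trp63 rose in p63beta keratinocytes from 183 ± 8.13 to 364 ± 24.3 CPM (SD, n = 3 each). The log2 fold change was 0.99 ± 0.09 (SE, edgeR adjusted p 0.0297), higher in 3 of 3 libraries, and with the replicate number as a block the adjusted p was 0.0451. The call was lost when any 1 of the 6 libraries was left out (log2 fold change 0.93 to 1.03, adjusted p 0.0661 to 0.307). In epidermis Trp63 measured 437 ± 159 and 640 ± 112 CPM (SD, n = 4 each), a log2 fold change of 0.55 ± 0.26 that did not pass (adjusted p 0.9999). The difference between these effects was not called either (-0.42 ± 0.33, adjusted p 0.99997).

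The next comparison asked which genes differ between p63beta and p63alpha keratinocytes. The basement membrane gene Nid2 (Entrez 18074) rose from 0.773 ± 0.235 to 109 ± 15.0 CPM (SD, n = 3 each), a 143-fold increase (log2 fold change 7.16 ± 0.24 SE, adjusted p 8.47e-04). The glutamate receptor gene Grm4 (Entrez 268934) rose from 0.398 ± 0.0175 to 9.66 ± 1.68 CPM, or 4.58 ± 0.24 on the log2 scale (adjusted p 0.00571). Trp73, a relative of Trp63, rose 4.64-fold from 2.31 ± 0.243 to 10.7 ± 1.06 CPM (log2 fold change 2.21 ± 0.18, adjusted p 0.0297). Log2 fold changes were 5.72 ± 0.55 for Fut9, 4.20 ± 0.36 for Npbwr1, 3.09 ± 0.24 for Socs2 and 2.90 ± 0.26 for Pgm2l1. They were 2.36 ± 0.22 for D630023F18Rik, 2.01 ± 0.17 for S100a3, 1.66 ± 0.15 for Cbr2, 1.39 ± 0.12 for Vsnl1 and 0.94 ± 0.07 for Antxr1 (SE). Tubb2b was the single gene that fell (log2 fold change -0.77 ± 0.08).

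In all, 14 of 13820 genes tested were called in keratinocytes, 13 higher and 1 lower, and 11 of them changed at least 2-fold. Every one of the 14 was higher, or for Tubb2b lower, in all 3 p63beta libraries than in all 3 p63alpha libraries. Such a lack of overlap was seen for 12.3% of all genes, against 10% by chance. Deviations from the group mean correlated at 0.624, 0.526 and 0.271 across 11560 genes for libraries sharing replicate number 1, 2 and 3. For different numbers, the correlation was 0.217 between p63alpha 3 and p63beta 2 and 0.209 between p63alpha 2 and p63beta 3. It was negative for the others (-0.534 to -0.332). The labels do not state pairs, and the pair numbered 3 is not clearly set apart. With the number as a block, 37 genes were called, 32 higher and 5 lower, among them 13 of the 14, and Npbwr1 was lost (adjusted p 0.0535). With the block and 1 pair left out, the 4 remaining libraries gave 585 genes without pair 1, among them all 37, but 1 without pair 3 and 0 without pair 2. Without pair 2, 687 of 14271 genes had an unadjusted p under 0.05 in edgeR, fewer than chance alone would give. The block added Lama5, Acta2, Klk8 and Bst2, each with a blocked adjusted p of 0.0431. Nid2 stayed called whichever library was left out (adjusted p at most 0.0164). The count fell to 4 without p63alpha library 1, to 1 without p63alpha library 2 or 3, to 3 without p63beta library 1, to 2 without p63beta library 2 and to 1 without p63beta library 3. The table of DESeq2 results that the authors deposited held 208 genes at an adjusted p under 0.05, 133 higher and 75 lower.

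**Figure D2:**
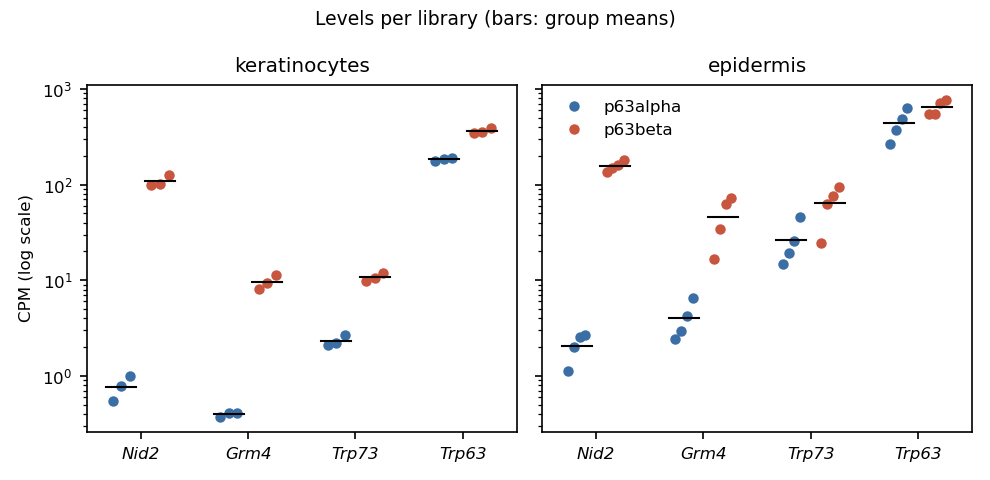
Level (CPM, log axis) of Nid2, Grm4, Trp73 and Trp63 in each library of keratinocytes (n = 3 per genotype) and epidermis (n = 4 per genotype). Points are libraries. Nid2 averaged 0.773 and 109 CPM in p63alpha and p63beta keratinocytes, and 2.07 and 156 CPM in epidermis.

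In keratinocytes, p63beta library 3 held muscle transcripts at levels far above the other 5 libraries. Myh6 stood at 1221 CPM there and at 10.1 to 27.8 CPM in the others, and Myl2 at 449 CPM against 4.73 to 13.1 CPM. Of 20 heart muscle genes listed after this was seen, 19 were highest in that library (95%, against 16.7% by chance). The fibroblast genes Dcn and Col3a1 were also highest there, with 51.5 and 42.1 CPM in that library against at most 2.68 and 4.58 CPM in the others. Their log2 fold changes of 3.30 ± 1.28 and 2.37 ± 1.03 (SE, adjusted p 0.699 and 0.730) were not called, and were 0.45 and 0.24 without that library. Acta2 (0.97 ± 0.25), Dct (-0.20 ± 0.50) and Pmel (-0.41 ± 0.48) were not called either (adjusted p 0.453, 0.977 and 0.951).

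**Figure D3:**
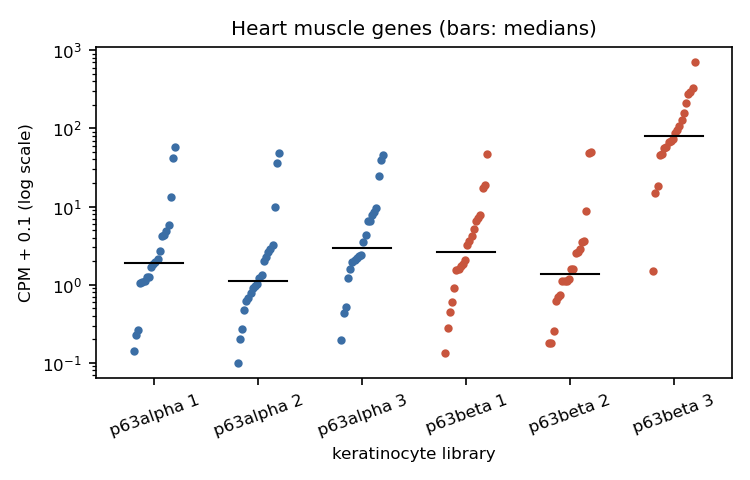
Level (CPM + 0.1, log axis) of heart muscle genes in each of the 6 keratinocyte libraries. Points are genes and bars are medians over the genes in a library. p63beta library 3 was highest for 19 of the 20 genes.

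The series title puts matrix genes in keratinocytes at the centre of the study, and the lists addressed that question. Of the 24 genes tested in the list of basement membrane and hemidesmosome genes, 24 had a positive log2 fold change, with a median of 0.49 (camera adjusted p 1.52e-22). In the matrix core list 61 of 83 were positive, with a median of 0.33 (adjusted p 1.12e-08), and in the collagens 20 of 24, with a median of 0.44 (adjusted p 2.83e-07). Laminin genes Lama5 and Lamb1 had log2 fold changes of 0.84 ± 0.16 and 0.94 ± 0.19, from 193 ± 25.8 to 345 ± 57.4 CPM and from 136 ± 24.4 to 260 ± 48.5 CPM (SE and SD, n = 3). Neither was called (adjusted p 0.289 and 0.325), nor were Plec (0.76 ± 0.17), Fras1 (1.02 ± 0.25), Col18a1 (0.67 ± 0.14), Col8a1 (0.98 ± 0.21), Col14a1 (1.96 ± 0.41) or Itga3 (0.66 ± 0.17), with adjusted p-values from 0.342 to 0.448. In the authors' table of DESeq2 results, Lama5, Lamb1, Fras1, Col18a1, Col8a1 and Col14a1 did pass (adjusted p 6.12e-04 to 0.0338). Lama3 (0.174), Col4a1 (0.133) and Hspg2 (0.240) did not pass there. DESeq2 as run here, however, called 59 unchanged genes in simulated keratinocytes. Over all genes tested with edgeR, Nid2 was the 1 called gene of the basement membrane list and of the matrix core list. Adjusted over the list alone, 9 of the 24 basement membrane genes were higher, or 17 with the block, and 6 of the 83 matrix core genes, or 7 with the block. At an estimated correlation none of these 3 lists was called (adjusted p 0.409 for each). Without p63beta library 3 the median of the matrix core list was 0.13 (adjusted p 1.02e-04) and that of the basement membrane list 0.44 (adjusted p 1.37e-19).

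Camera at the preset correlation called 19 of 33 lists in keratinocytes, 14 higher and 5 lower. Among the other higher lists were basal keratinocytes (median 0.27, adjusted p 2.17e-05), targets of YAP and TEAD (0.24, 4.25e-05), matrix glycoproteins (0.14, 4.25e-05), endothelium (1.27, 4.25e-05), integrins and matrix receptors (0.26, 0.00189) and proteoglycans (0.78, 0.0293). At an estimated correlation each of these had an adjusted p of 0.409. The lists of fibroblast matrix genes (0.33, adjusted p 0.0107), keratinocyte cytokines (0.34, 0.0146) and TGF-beta response (0.14, 0.0299) were higher and had an adjusted p of 0.581 at an estimated correlation. Collagen crosslinking enzymes (0.28, adjusted p 0.0142) and pericytes (0.63, 0.0187) were also higher, with adjusted p-values of 0.450 and 0.474 at an estimated correlation.

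The 5 lower lists were desmosomes (median -0.22, adjusted p 1.45e-05), adherens and tight junctions (-0.11, 4.25e-05), interferon response (-0.73, 2.17e-05), early suprabasal differentiation (-0.22, 0.00952) and late differentiation (-0.29, 0.0142). At an estimated correlation their adjusted p-values were 0.409, 0.409, 0.581, 0.550 and 0.642. Among their members, Dsc2 (-0.74 ± 0.13), Cldn3 (-0.77 ± 0.12), Notch3 (-0.88 ± 0.17), Tgm1 (-0.83 ± 0.17), Sprr2h (-0.64 ± 0.12), Klk8 (-0.80 ± 0.17), Bst2 (-1.36 ± 0.85) and Irf9 (-1.07 ± 0.66) were not called. Adjusted over the list alone, 0 of 31 interferon genes were lower with edgeR, but 18 with the block, and 3 of 41 late differentiation genes, or 11 with the block. Krt6a (-0.71 ± 0.17, adjusted p 0.412) was not called. Without p63beta library 3, 12 of the 19 lists stayed called. The 7 lost were crosslinking enzymes, early suprabasal differentiation, fibroblast matrix genes (median -0.07 without it), late differentiation (0.14), pericytes, proteoglycans and TGF-beta response. The endothelium median was 1.27 with that library and 0.19 without it, although Mmrn2 (5.84 ± 0.76, adjusted p 0.108) and Pecam1 (1.85 ± 0.49, adjusted p 0.470) had no overlap between groups. Neither was called.

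When each of the 6 keratinocyte libraries was left out in turn, 10 of the 19 lists stayed called every time, and 9 lost their call without at least 1 library. These fits ignore the replicate number. Interferon response lost its call without p63alpha library 1 (adjusted p 0.841, medians -2.55 to 0.38), which leaves p63beta library 1, also high in these genes, without the p63alpha library of the same number. Within each pair the mean log2 CPM of this list was lower in p63beta: 4.38 and 3.57, 2.22 and 0.78, and 2.15 and 1.08 in p63alpha and p63beta libraries 1, 2 and 3. Late and early suprabasal differentiation lost it without p63alpha library 1 or p63beta library 2 or 3 (medians -1.47 to 0.93 and -0.78 to -0.03). Without p63alpha library 1 or p63beta library 3, fibroblast matrix genes and pericytes were not called, nor proteoglycans, which were also lost without p63alpha library 2. Crosslinking enzymes were lost without p63alpha library 2 or p63beta library 3, and TGF-beta response without either of these or p63beta library 2. Keratinocyte cytokines were lost without p63alpha library 2 or 3 or p63beta library 2. With the block and 1 pair left out, 14 of the 19 lists stayed called at the preset correlation every time, among them interferon response (adjusted p at most 5.44e-17, medians -1.35 to -0.99). With the block, all pairs and an estimated correlation, the adjusted p of that list was 0.462. The lists lost were cytokines without pair 2 or 3, TGF-beta response without pair 2, and fibroblast matrix genes, pericytes and proteoglycans without pair 3.

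Lists not called in keratinocytes included targets of p53 (median 0.12, adjusted p 0.0564), which was called with the block at the preset correlation (0.00412). No list was called with the block and an estimated correlation. Cdkn1c (1.85 ± 0.25, adjusted p 0.121) and Fjx1 of the YAP list (0.91 ± 0.11, adjusted p 0.0827) were not called. For 4 lists that were not called, median, mean and camera differed in sign. These were the genes reported as regulated by p63 (median -0.00, mean 0.08, higher in camera), Merkel and simple epithelial cells (0.24, 0.02, lower), wound-activated keratinocytes (0.04, -0.01, lower) and myeloid cells (-0.09, 0.07, lower).

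In epidermis the same question was asked of tissue. Nid2 rose from 2.07 ± 0.697 to 156 ± 18.6 CPM (SD, n = 4 each), a 75.5-fold increase (log2 fold change 6.24 ± 0.28 SE, adjusted p 7.81e-06). The kinase gene Stk32a rose from 0.0237 ± 0.0159 to 11.5 ± 3.13 CPM (log2 fold change 8.62 ± 0.49, adjusted p 3.37e-05). The neuropeptide receptor gene Npbwr1 rose from 11.3 ± 3.04 to 99.6 ± 11.04 CPM (3.14 ± 0.23, adjusted p 2.54e-04), and the cell cycle inhibitor gene Cdkn1c from 7.95 ± 3.68 to 78.9 ± 26.2 CPM (3.31 ± 0.35, adjusted p 0.00397). Myot was at 0 in all 4 p63alpha libraries and averaged 5.32 ± 4.37 CPM in p63beta, at least 52.7-fold higher against a floor of 3 counts per library, or at least 31.4-fold without EP12, the highest library. Log2 fold changes were 6.32 ± 0.78 for Epha3, 5.58 ± 0.66 for Sncg, 5.51 ± 0.74 for Fut9, 5.37 ± 0.50 for D630023F18Rik and 4.15 ± 0.62 for Ptgs2 (SE). They were 4.06 ± 0.49 for Dpp6, 3.55 ± 0.58 for Camk4, 3.54 ± 0.49 for Grm4 and 1.13 ± 0.17 for Axl. Slc16a14 (-2.91 ± 0.42) and Pdzrn4 (-2.71 ± 0.36) fell.

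In all, 32 of 13796 genes tested were called in epidermis, 30 higher and 2 lower, each changed at least 2-fold and each without overlap between the 4 and 4 libraries. Such a lack of overlap was seen for 3.07% of all genes, against 2.86% by chance. With batch as a term 38 genes were called, among them 29 of the 32, and Myot was lost. The first batch alone gave 8, all among the 32. Nid2, Stk32a, Npbwr1, Cdkn1c, D630023F18Rik and Sncg stayed called whichever library was left out, with adjusted p-values of at most 0.0465. The count fell to 10 without EP07, 19 without EP08, 18 without KO2, 16 without EP10 and 18 without EP11. The authors' table held 144 genes, 109 higher and 35 lower.

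Among the lists in epidermis, melanocyte genes had the lowest p: 14 of 14 had a positive log2 fold change, with a median of 1.05 (camera adjusted p 7.07e-19, or 0.312 at an estimated correlation). Adjusted over the list alone, 9 of the 14 were higher. Dct measured 97.5 ± 32.7 and 197 ± 29.0 CPM (log2 fold change 1.02 ± 0.24), and Ednrb (1.13 ± 0.24), Pmel (1.08 ± 0.31), Tyr (0.97 ± 0.28) and Tyrp1 (1.66 ± 0.50) were similar, but none was called over all genes (adjusted p 0.157 to 0.594). The matrix core list was not called (39 of 86 positive, median -0.07, mean 0.03, camera higher, adjusted p 0.343, or 0.868 at an estimated correlation). In it, 1 gene was called, Nid2, and 1 was higher adjusted over the list alone. Without Nid2 its direction in camera was lower (adjusted p 0.866). The list was called higher without EP09 (adjusted p 0.00264) and lower in the first batch alone (adjusted p 0.0347). Lama5 (0.54 ± 0.24), Tinagl1 (1.498 ± 0.37), Fbln2 (-0.86 ± 0.26) and Col14a1 (-1.08 ± 0.42) were not called.

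Camera at the preset correlation called 14 of 34 lists in epidermis, 10 higher and 4 lower. Wound-activated keratinocytes (median 0.79, adjusted p 3.89e-07), basement membrane (0.08, 3.89e-07), late differentiation (0.22, 8.08e-05) and adipocytes (0.67, 0.0298) were higher, and fibroblast matrix genes (-0.64, 3.38e-05) were lower. Each of these 5 had an adjusted p of 0.588 at an estimated correlation. Targets of p53 (0.21, adjusted p 0.00166) were higher, with 0.254 as the adjusted p at an estimated correlation. Schwann cells and neurons (0.67, adjusted p 0.0190), targets of YAP and TEAD (0.03, 0.0302) and crosslinking enzymes (0.26, 0.0302) were higher, with an adjusted p of 0.618 at an estimated correlation. T cells (-0.54, adjusted p 0.00166, 15 of 15 negative), myeloid cells (-0.27, 0.0199) and hair follicle genes (-0.48, 0.00232, 34 of 36 negative) were lower, with adjusted p-values of 0.705, 0.705 and 0.688 at an estimated correlation. Matrix glycoproteins were called higher (adjusted p 0.0302, or 0.745 at an estimated correlation) with a median of -0.08 and a mean of 0.15. Single genes carried 3 of these calls: without Nid2, the adjusted p was 0.729 for matrix glycoproteins (mean 0.03) and 0.0638 for basement membrane, and without Axl it was 0.214 for targets of YAP and TEAD.

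When each of the 8 epidermis libraries was left out in turn, 5 of the 14 lists stayed called every time: melanocytes, wound-activated keratinocytes, late differentiation, targets of p53 and fibroblast matrix genes. Basement membrane lost its call without WT3 (adjusted p 0.108, median -0.07), and hair follicle genes without EP09 (0.418) or EP12. T cells lost it without EP09 or EP10 (at most 0.107), and myeloid cells without EP07, WT3, EP09, KO2 or EP10 (at most 0.460). Adipocytes lost it without EP07, WT3 or EP12 (at most 0.178), Schwann cells and neurons without WT3 or KO2 (at most 0.302), and targets of YAP and TEAD without WT3 or EP11 (at most 0.552). Crosslinking enzymes lost it without EP08, WT3, KO2 or EP10 (at most 0.322), and matrix glycoproteins without WT3, KO2, EP10 or EP12 (at most 0.727).

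In the first batch alone 9 of the 14 lists were not called. These were basement membrane (median -0.13, adjusted p 0.276), late differentiation (0.22, 0.102), adipocytes (0.61, 0.262), crosslinking enzymes (0.25, 0.276), targets of YAP and TEAD (0.01, 0.336), Schwann cells and neurons (0.23, 0.808), T cells (-0.29, 0.200), myeloid cells (0.01, 0.708) and matrix glycoproteins (-0.14, 0.616, lower in camera). Without WT3 and EP12, 5 were not called: adipocytes (adjusted p 0.264), crosslinking enzymes (0.146), targets of YAP and TEAD (0.323, median -0.05), Schwann cells and neurons (0.0551) and matrix glycoproteins (0.895, lower in camera). With batch as a term all 14 were called at the preset correlation, and none at an estimated one (camera adjusted p at least 0.358).

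Of the members of the 14 called lists, Nid2 and Axl were called, and the genes that follow were not. Krt6a (2.87 ± 1.31) and Krt6b (3.19 ± 1.49) varied widely among p63beta libraries, with 1294 ± 894 and 1731 ± 1140 CPM (SD, n = 4). The others were Sprr1a (0.94 ± 0.40), Cnfn (0.78 ± 0.33), Eda2r (1.69 ± 0.38), Gata3 (-0.43 ± 0.15), Lef1 (-0.84 ± 0.36), Csf1r (-0.74 ± 0.34) and Laptm5 (-0.54 ± 0.35). Besides the matrix core list, median, mean and camera differed in sign for 5 lists that were not called. These were proteoglycans (median -0.02, mean 0.11, higher), endothelium (0.21, -0.02, higher), interferon response (-0.02, 0.06, higher), cell cycle (0.01, 0.03, lower) and erythroid cells (0.11, 0.07, lower).

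**Figure D4:**
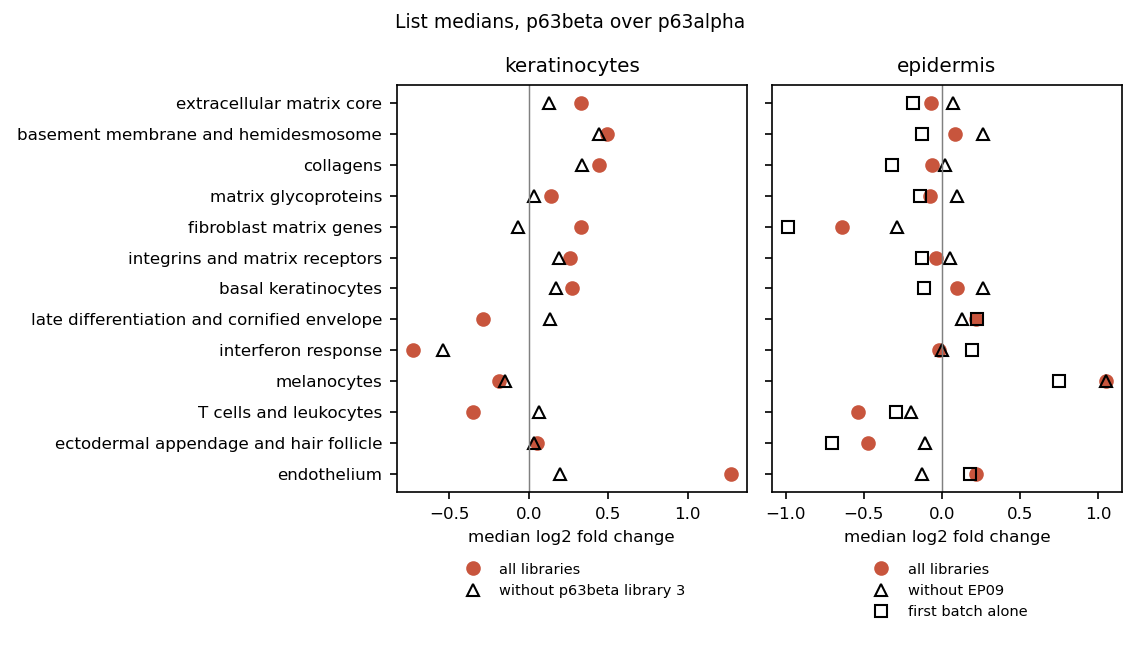
Median log2 fold change of p63beta over p63alpha for 13 gene lists in keratinocytes and epidermis. Filled circles use all libraries, and open symbols leave out p63beta library 3 in keratinocytes, or EP09 or the second batch in epidermis. The matrix core list had medians of 0.33 in keratinocytes and -0.07 in epidermis.

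Both kinds of sample were then compared for shared changes. Of 12667 genes tested in both, 5 were called in both and all 5 were higher: Nid2, Fut9, Grm4, Npbwr1 and D630023F18Rik. By chance 0.0287 would be called higher in both. The log2 fold changes correlated across genes with a Pearson r of 0.235 and a Spearman rho of 0.0816, and genes are not independent replicates. Of the 37 genes called in at least 1 kind of sample, 34 had the same sign in both. Leaving out any 1 keratinocyte library left 1 to 3 genes called in both, and leaving out any 1 epidermis library left 3 to 5.

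**Figure D5:**
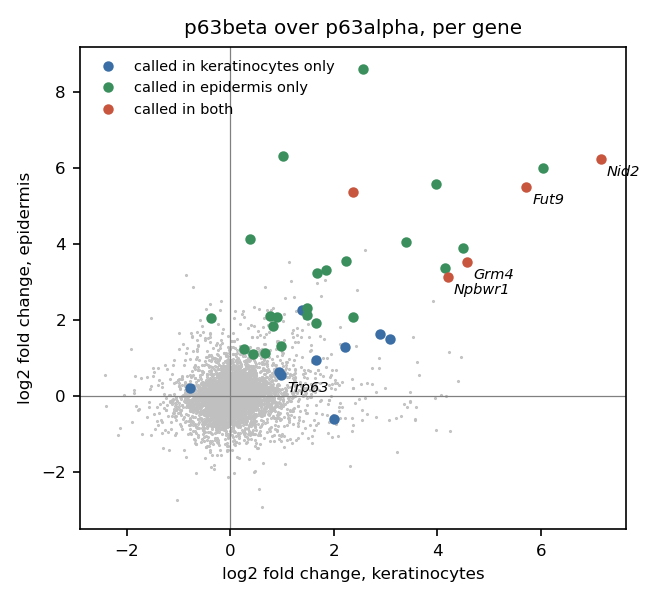
Log2 fold change (p63beta over p63alpha) in keratinocytes against that in epidermis for genes tested in both. Points are genes, and coloured points are genes called in keratinocytes, in epidermis or in both. The 5 genes called in both lie at the upper right.

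Whether the effect of the genotype differed between epidermis and keratinocytes was tested directly. With edgeR, 0 of 14740 genes were called and 619 had an unadjusted p under 0.05, fewer than chance alone would give. Limma voom called 0. Among genes with the lowest p, the effect was larger in epidermis for Kif26b (difference of log2 fold changes 2.44 ± 0.44), Ptgs2 (3.79 ± 0.72), Tafa5 (2.60 ± 0.54), Stk32a (6.06 ± 1.33) and Epha3 (5.31 ± 1.21). The difference was negative for Myo16 (-7.75 ± 1.19), Pdzrn4 (-4.59 ± 0.84), Chst2 (-2.34 ± 0.47), Pm20d2 (-1.57 ± 0.33) and Pcyt1b (-2.02 ± 0.42). None of these differences passed (adjusted p 0.369 to 0.842). A negative difference is not a smaller effect, as Pdzrn4 was a called fall in epidermis (log2 fold change -2.71 ± 0.36). Camera at the preset correlation called the difference for 19 of 35 lists, and at an estimated correlation for 0, with adjusted p-values of at least 0.475. The matrix core list was lower in epidermis by a median difference of -0.41 (adjusted p 6.08e-06, or 0.475 at an estimated correlation). Its keratinocyte median was 0.33 with p63beta library 3 and 0.13 without, and the difference was not tested without that library.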

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

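The tests of other tissue, fibroblasts, keratinocyte share and hair follicles given in this part were chosen after the results they address were seen, and the tests of batch and of other splits before, although batch itself was taken up after the data were seen. A condition that a lower list must hold without EP09 was added after the first output. It left the hair follicle explanation open, where the test had argued against it before, and in the test of keratinocyte share it was asked of the fibroblast matrix list alone, whose median was then printed in place of that of the T cells. The quartiles, and the counts among splits that part numbered pairs or batches, were also added after these results were seen.

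Within the groups of 4 epidermis libraries, 146 groups of values were tested for a library far from the other 3, and 15 (10.3%) held one. Chance flags about 1 in 20 groups. The numbers that follow are the gap to the nearest other library as a share of the whole range. In p63alpha, WT3 lay below the others for Lama5 (0.943), Fbln2 (0.873) and the means of the lists of basement membrane (0.873), endothelium (0.833), matrix proteases (0.868), genes reported as regulated by p63 (0.890) and TGF-beta response (0.857). EP09 lay below for Stk32a (0.899) and above for Dpp6 (0.967), and EP08 below for Laptm5 (0.840). Stk32a stood at 0 CPM in EP09 and at 0.0294 to 0.0334 CPM in the other p63alpha libraries. These values are all below the floor of 0.101 CPM given for Myot, so that gap does not set EP09 apart. In p63beta, EP12 lay below for Epha3 (0.900), Krt6a (0.911) and Krt6b (0.991) and above for Dpp6 (0.845). In KO2 the alpha ending of Trp63 carried 11.7%, against 2.15% to 2.90% in the other p63beta libraries (0.921). No explanation was tested for these libraries. Groups of 3 keratinocyte libraries were too small for this test.

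The difference between the genotype effects in epidermis and in keratinocytes was called by camera at the preset correlation for 19 lists, and for none of them at an estimated correlation (adjusted p 0.475 in each case). The log2 fold change was higher in epidermis for melanocytes (median difference of log2 fold changes 1.30, adjusted p 5.56e-15), interferon response (0.82, 7.59e-06), wound-activated keratinocytes (0.88, 7.52e-05), late differentiation (0.50, 8.06e-04), adherens and tight junctions (0.18, 0.0110), desmosomes (0.31, 0.0261) and early suprabasal differentiation (0.29, 0.0261). A higher value is not always a larger effect. Medians in keratinocytes and epidermis were -0.73 and -0.02 for interferon response, and -0.22 and -0.03 for early suprabasal differentiation. For wound-activated keratinocytes they were 0.04 and 0.79. The log2 fold change was lower in epidermis for fibroblast matrix genes (-1.30, 1.41e-09), basement membrane (-0.35, 1.29e-06), collagens (-0.66, 1.29e-06), the matrix core list (-0.41, 6.08e-06) and T cells (-0.42, 0.00437). It was also lower for hair follicle genes (-0.40, 0.00710), fibroblasts outside the matrix list (-0.70, 0.00765), matrix glycoproteins (-0.27, 0.00863), integrins (-0.29, 0.0104), endothelium (-0.84, 0.0261), matrix proteases (-0.17, 0.0327) and proteoglycans (-1.36, 0.0407). For some lists the keratinocyte median depended on the p63beta library that held muscle transcripts. With and without it, medians were 0.33 and -0.07 for fibroblast matrix genes, 1.27 and 0.19 for endothelium, and 0.78 and 0.28 for proteoglycans. For late differentiation they were -0.29 and 0.14. For basement membrane (0.49 and 0.44) and collagens (0.44 and 0.34) they moved less. The differences between epidermis and keratinocytes were not tested without that library. Of 40 splits, 12 gave at least as many lists (19 for the real split, 24 at most in another), so chance is not excluded for that count. For single genes the real split gave 0, so that 40 of 40 splits gave at least as many by construction and the comparison decides nothing (14 at most in another). Beside the 0 of edgeR, 619 of 14740 genes had an unadjusted p under 0.05, fewer than chance alone would give, and limma voom called 0.

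Matrix genes in p63beta keratinocytes form the first pattern weighed, which holds at the preset correlation and not at an estimated one (adjusted p 0.409, or 0.469 with the block). At the preset correlation, the tables argue against RNA from another tissue in p63beta library 3 as the whole cause, since the matrix core list stayed higher without that library (adjusted p 1.02e-04), but it may account for part, as the median was 0.33 with it and 0.13 without. The list also stayed higher without the fibroblast matrix genes (adjusted p 1.37e-08). That cannot exclude more fibroblasts in the p63beta cultures, which could raise the matrix genes left in the list too. Without p63beta library 3, the medians of fibroblast matrix genes and of fibroblasts outside the matrix list were -0.07 and -0.06 (camera adjusted p 0.922 each). In the remaining libraries, the matrix core list was thus higher without a rise of those lists. The 10 splits of the 6 libraries are too few for a share under 0.05: 2 gave a camera p as low, with 6.78e-10 for the real split and 3.79e-10 as the lowest of the others, which keeps 2 pairs of equal numbers together, and 5.75e-09 as the lowest of the 3 others that part every pair. An effect of the genotype stays open.

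Melanocyte genes in p63beta epidermis form the second pattern, which was not called at an estimated correlation (adjusted p 0.312, or 0.567 with batch as a term), but at the preset one was called in the first batch alone (4.30e-09, median 0.75) and with batch as a term (1.89e-16), which argues against batch as the whole cause. A lower share of keratinocytes would raise other cell types alike, and adipocytes (0.67, adjusted p 0.0298) and Schwann cells and neurons (0.67, 0.0190) were higher too, but the fibroblast matrix median was -0.64, and -0.86 to -0.29 with any 1 library left out (at most 0.0420, though 0.588 at an estimated correlation). That argues against this explanation at the preset correlation, but rests on 1 of the 3 lists tested, as T cells and myeloid cells, also called lower, lost their calls without EP09 (0.107 each). The T cell median was -0.54 with all libraries and -0.20 without EP09. The myeloid median was -0.27 in both cases, but that list also lost its call without each of several other libraries. More hair follicles remain possible, as the exclusion rests on EP09: the hair follicle median was -0.48 and the upper quartile -0.27, but without EP09 they were -0.11 and 1.23, so that some members rose as much as melanocyte genes, and more melanocytes were not separated from more expression in each. Of 35 splits 1, the real one, gave a camera p as low as 2.08e-20. This list had the lowest p of all lists for the real split, and other splits were scored on it alone. That share therefore does not exclude chance. The 20 splits that part WT3 and KO2, as the real one does, are too few for a share under 0.05. Of these, 1, which exchanged EP08 for EP11, gave 2.41e-20.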

How the results depend on the processing

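The term for batch, the first batch alone, leaving out WT3 and EP12 together, the block without each pair, the block with an estimated correlation and the matrix list without Nid2 were chosen after the data were seen. Where no cause is named, the cause was not tested.

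In keratinocytes 14 genes were called, 14 with RLE size factors, 13 without a filter on low counts and 11 to 16 with limma on log2 FPKM. Leaving out 1 library, which leaves fewer samples, gave 1 to 4 genes. DESeq2 called 224, including the 14, but in simulated data it also called 59 unchanged genes. The Trp63 log2 fold change was 0.93 to 1.03 when 1 library was left out, with the call lost each time. Lists called numbered 19, 12 to 28 when 1 library was left out (12 without p63beta library 3), and 0 with an estimated correlation or with fry. The matrix core list stayed called with RLE, no filter, the block, without Nid2 and without any 1 library (adjusted p 2.74e-14 to 1.02e-04). It was lost with an estimated correlation (0.409), also with the block (0.469).

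The replicate number as a block raised the keratinocyte count to 37 genes, with 13 shared. With the block and 4 libraries, however, the count was 585 without pair 1, 1 without pair 3 and 0 without pair 2. In the last of these, 687 genes had an unadjusted p under 0.05, fewer than chance alone would give. Lists numbered 20 with the block and 0 with the block and an estimated correlation. No paired analysis was possible in epidermis because the count columns do not say which library carries which replicate number of the labels.

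In epidermis 32 genes were called, 34 with RLE, 33 without a filter and 24 with limma on log2 TPM. Leaving out 1 library gave 10 to 28, the first batch alone, with fewer samples, gave 8, and DESeq2 gave 141, including the 32, with 34 unchanged genes called in simulated data. Lists numbered 10 to 15 when 1 library was left out, and 0 with an estimated correlation or fry. The matrix core list, not called with all libraries (0.343), had an adjusted p of 0.00264 to 0.523 when 1 library was left out. It was called higher without the fibroblast matrix genes (0.00207) and without EP09, and lower in the first batch alone (0.0347). Its direction was also lower, without a call, without WT3 (0.0998), without WT3 and EP12 (0.251) and without Nid2 (0.866).

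Genes called in both kinds of sample numbered 5, 1 to 5 when 1 library was left out, 6 with the block and 27 with DESeq2. The correlation of fold changes was 0.235, 0.140 to 0.279 when 1 library was left out, 0.0918 without a filter, which adds genes with few counts, and 0.579 over the genes called in at least 1 kind of sample. The interaction called 0 genes under every alternative run. The alpha share of Trp63 differed by -77.9 percentage points, -80.2 to -77.0 when 1 library was left out and -81.7 from transcript counts.

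Reversals among the genes recomputed were all in genes without a call. In keratinocytes, Dct (-0.20) was 0.25 without p63alpha library 3 and 0.027 with the replicate block (-0.63 to 0.25 over libraries left out). Pmel (-0.41) was 0.041 without p63alpha library 3 (-0.83 to 0.041). Ckm (4.12) was -0.36 without p63beta library 3, which held the muscle transcripts (-0.36 to 4.83). Of 27 keratinocyte genes named as not called, 20 were called with DESeq2, as were 5 of 18 in epidermis besides Trp63. Leaving out 1 library kept the call of 1 to 3 of the 13 genes called in keratinocytes besides Trp63, and of 6 to 14 of 16 genes named as called in epidermis, Kif26b not counted.

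Depth sets a floor for genes without counts, 0.101 CPM for Myot in epidermis. At the depth and spread of these libraries, simulated changes of 1 on the log2 scale were recovered by edgeR for 47.8% of genes in keratinocytes and 32.8% in epidermis.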

Other observations

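The tests of muscle transcripts in this part were chosen after these were seen, and the heart gene list was written then. The counts of splits were set before, and those among splits that part numbered pairs or batches were added after.

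Muscle transcripts in p63beta keratinocyte library 3 form the third pattern weighed. RNA from heart muscle may explain them, since 95% of the listed genes were highest in that library, with a median of 5.65 on the log2 scale over the other 5. Besides Myh6 and Myl2, Myh7 stood at 99.7 CPM, Nppa at 51.8 CPM and Ckm at 162 CPM, against at most 1.65, 1.28 and 5.74 CPM in the others. The tables argue against an effect of the genotype, because in the other p63beta libraries the median log2 ratio over p63alpha was -0.13 (quartiles -0.34 and 0.12). The library also held 15.1 CPM of Hbb-bs, against at most 0.988 CPM. How such RNA came to be there was not tested.

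Other splits of the libraries into groups of the same size were fitted in the same way. In keratinocytes 10 splits are too few for a share under 0.05: the real split gave 14 genes and 19 lists, and the most in another were 0 genes and 23 lists. The splits with as many lists as the real one numbered 3, and 2 gave as low a p for the matrix core list. Of the 4 splits that part every pair of equal numbers, the 3 others gave 0 genes with and without the block, at most 17 lists, and a p for the matrix core list of at least 5.75e-09 (6.78e-10 for the real split). For the basement membrane list the real split gave a camera p of 4.60e-24, the lowest of 10, against 4.04e-14 in another. In epidermis 1 of 35 splits, the real one, gave 32 genes, with 15 at most in another, so chance is excluded for that count if batch is set aside. The 20 splits that part WT3 and KO2, as the real one does, are too few for a share under 0.05 (15 at most in another of these). It is not excluded for the number of lists, as 11 of 35 splits gave 14 or more (22 at most in another). Nor is it for the matrix core list in epidermis, as 24 of 35 gave a p as low (0.232 for the real split, 2.03e-12 at the lowest in another). For genes called in both kinds of sample, 1 of 100 drawn pairs of splits gave as many (5 for the real pair, 0 at most in another). In 92 of them the keratinocyte split called no gene and could share none, so this comparison decides nothing. For the correlation of fold changes, 1 of 100 gave as large a value (0.235, with 0.147 at most in another), so chance is excluded for that value. Among the 80 pairs of splits that part every numbered pair as well as WT3 and KO2, 1 gave as large a value too (0.162 at most in another). The number of lists called in epidermis at the preset correlation was therefore not above that of arbitrary groupings of the same libraries.

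The first principal component of the keratinocytes carried 40.4% of the variance and set the libraries numbered 1 of both genotypes apart from the other 4. These held more Isg15, with 113 CPM in p63alpha and 33.3 CPM in p63beta, against 9.93 CPM or less in the others. In epidermis the first component carried 32.3% and set WT3 and EP12 apart. These had the lowest Krt14 of their groups, with 1849 and 1752 CPM, and the lowest Krt6a, with 5.08 and 21.8 CPM. EP09 and EP11 held 84.2 and 99.6 CPM of the Y-linked gene Ddx3y, and the other 6 epidermis libraries at most 5.57 CPM. All 6 keratinocyte libraries held both Xist (at least 327 CPM) and Ddx3y (at least 9.43 CPM).

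In p63beta epidermis, the 1 transcript with the alpha ending that had any TPM was 12 nt shorter than the longest one, which was at 0 TPM in all 4 p63beta libraries and between 37.5 and 107 TPM in p63alpha. The shorter transcript stood between 6.16 and 19.6 TPM in p63beta.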
